A study of Mus musculus with 4 samples.

How the data were processed

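Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of TLE3, a corepressor of the Groucho family, was measured in primary mouse adipocytes from 3 fat depots. Stromal-vascular cells were taken from epididymal white fat (eWAT), inguinal white fat (iWAT) and pooled brown fat (BAT) of male mice aged 4 to 5 weeks, with 10 to 15 mice per pool, per the labels' protocols. They were differentiated in culture with 30 nM insulin and 1 µM rosiglitazone, a PPARγ agonist, and harvested on day 8, and cultures with over 50% differentiation were kept, per the labels' protocols. Chromatin was fixed with 2 mM disuccinimidyl glutarate for 15 min and then 1% formaldehyde for 30 min, per the labels' protocols. The 4 libraries were 1 TLE3 library per depot and 1 input library from iWAT adipocytes.

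STAR, HOMER and the mm9 build are named by the submitters' processing notes without version or role. Each deposited table listed regions with 230 bp between start and end, the nearest gene, an annotation, the distance to the nearest transcription start site, and a value for the input and for each of the 3 TLE3 libraries, per the file headers. The header has the layout of HOMER's peak annotation output. The deposited values were a signal, reads in the region scaled by the authors to one total per library. The deposited peak score was 0 in every line and ranked nothing, so each library's own scaled value took its place for ranking and filtering, which departs from the design fixed before the data were examined. How peaks were called, and against which control, is not given in the sources used here.

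Within each library every value was a whole multiple of 1 step, and 100% of the values came out as whole reads within 0.1 read. One read was worth 0.883 scaled reads in eWAT, 0.526 in iWAT, 2.77 in BAT and 0.651 in the input. If the scale was 10 M reads, HOMER's default and an assumption here, the libraries held 11.3 M, 19.0 M, 3.62 M and 15.4 M reads in that order. Every listed region had at least 15 scaled reads in its own library and at least 10 times the input value. In iWAT and BAT, 0 regions of the merged set met both limits without being listed, and in eWAT 9 did. The limits are thus read from the values and are not stated by a source. At the lower limit a region rested on 17 reads in eWAT, 29 in iWAT and 6 in BAT. A value of 0 reads allows up to 3 reads, or 2.65, 1.58 and 8.30 scaled reads in the 3 libraries.

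The 3 lists were joined into one set of 69599 regions. Lists were compared by overlap of at least 1 bp, with shares set beside 100 random placements of the same number of regions on the same chromosomes, up to the last listed position. Equal-sized lists took the strongest regions of each list, as many as the BAT list holds. Selective regions were those in the strongest 25% of their own list that overlapped no region of the other 2 lists. Positions relative to genes came from the deposited annotation. Shares carry Wilson 95% intervals. These and all other intervals cover counting error only.

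For each region, the reads of 2 libraries were compared with an exact binomial test on both sides, with Benjamini-Hochberg adjustment over all regions at 0.05. The expected split was set by the median ratio over the strongest 25% of regions by mean value. The test compares those libraries, not the conditions, because each depot has 1 library. Other scalings were also run, the authors' own and the median ratio of the regions listed in all 3 depots.

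A gene was given the regions within 50 kb of its start site, where the deposited table named it as the nearest gene. A region nearer to another start site was therefore not counted, and a gene could have no region by this rule. Gene ratios are log2 ratios of summed scaled reads minus the median gene's log2 ratio, with exact Clopper-Pearson intervals on the reads. A gene is called higher or lower only where its whole interval lay on one side under every scaling, which were the authors', the strongest 25%, the common regions, all regions and the median gene. Genes with a mean of at least 30 scaled reads over the 3 libraries, 9099 of 13381, entered list comparisons.

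The 18 gene lists covered adipocyte identity and lipid storage, brown and beige thermogenesis, white-selective genes, depot-developmental factors, nuclear oxidative phosphorylation, mitochondrial biogenesis and dynamics, fatty acid oxidation, glucose uptake with glycolysis and insulin signalling, Wnt-TCF and Notch targets, the Groucho/TLE family, adipocyte transcription factors and coregulators, and 7 lists of other cell types. The 7 were preadipocyte and fibroblast, mesothelial, macrophage, endothelial, skeletal muscle, neuronal and hepatocyte. The lists held 438 genes, of which 32 stood in more than 1 list. A second macrophage list, a T and NK cell list and a B cell list were added later. For each list, the share of genes with a listed region was set beside 10000 random lists of the same size drawn from 20953 protein-coding genes and matched on gene length and on the number of genes within 500 kb. The median log2 ratio, with a pseudocount of 5 scaled reads, was set beside 10000 random lists matched on mean value in 10 classes. Percentiles describe these libraries and are not p-values. Of 14265 gene identifiers in the tables, 14249 (99.9%) matched the reference gene table of assembly GRCm38.p6. That table was used for names, gene lengths and neighbour counts, and none of its coordinates is printed.

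The genes named in the text follow a rule. The common set holds the 2 genes of each of the 11 lists that are not of other cell types that rank highest by their strongest region, by the sum of ranks over the 3 depots, among genes with a listed region in all 3. The depot set holds up to 8 listed genes per depot with the strongest selective region. Tle3, Pparg, Ebf2, Prdm16, Ucp1, Cidea, Ppargc1a, Adipoq, Fabp4, Lep, Zic1, Lhx8, Tbx15, Wt1, Hoxc9, Axin2 and Hes1 are always named. Every other named gene was chosen after its values were seen, and the text says so.

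Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The region test was tested on simulated reads. These were drawn with counting error alone around the mean of the 2 libraries at each of the 69599 regions. Changes were planted upward and in the stronger regions only, and the expected split was given rather than estimated. Of 100 regions changed by 4-fold, it called 100% for eWAT over iWAT, 94% for BAT over eWAT and 96% for BAT over iWAT. Of 100 changed by 2-fold it called 83%, 9% and 19%. It called 5, 2 and 2 unchanged regions, which does not measure false calls from variation between libraries or from the scaling. In the list comparison over 9099 genes, a planted list lay at percentile 99.95, and 1 of 40 unchanged lists fell outside the central 95%.

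Alternatives varied the overlap that counts as shared, the fold over the input, the ranking measure, the list size, the distance to start sites, the pseudocount, the filter on low values, the matching of random lists and the scaling. Motifs, shares at random positions of the annotation and the fold over local background were not analysed here, because they need an mm9 genome sequence, an mm9 annotation or a local background value.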

Results

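TLE3-bound regions were collected from cultured primary adipocytes of 3 mouse fat depots, epididymal white fat (eWAT), inguinal white fat (iWAT) and brown fat (BAT). Cells were differentiated with insulin and rosiglitazone and harvested on day 8, with 1 TLE3 ChIP-seq library per depot and 1 input library from iWAT. There were no replicates, so depot and library cannot be told apart. Read depth differed between libraries. The values imply 11.3 M reads for eWAT, 19.0 M for iWAT, 3.62 M for BAT and 15.4 M for the input if values were scaled to 10 M. Together the 3 lists held 69599 regions. On the same assumption, these regions took up 26.2% of the eWAT reads, 26.3% of the iWAT reads, 10.1% of the BAT reads and 1.13% of the input reads. The BAT list gave 15042 of the regions, against 51015 for eWAT and 50456 for iWAT. The BAT share was thus taken mostly at regions not listed in BAT. All intervals given are 95% intervals for counting error alone, values are scaled reads, and coordinates are of the mm9 build.

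TLE3 bound its own gene in all 3 depots. The region at Tle3 on chromosome 9 from 61218230 to 61218460, 1.83 kb from the start site and annotated as intergenic, had 298 scaled reads in eWAT, 176 in iWAT and 135 in BAT. Tle2, another Groucho family gene, had a region on chromosome 10 from 81033587 to 81033817, annotated as intergenic, with 277, 185 and 113. Pparg encodes the nuclear receptor that drives fat cell differentiation. Its strongest region, on chromosome 6 from 115402629 to 115402859 and annotated as intronic, had 214, 236 and 102. Mgll encodes a lipase that releases fatty acids from monoglycerides, and its intronic region on chromosome 6 from 88696382 to 88696612 had 269, 219.7 and 124. The highest value of any region lay 39.0 kb from the start site of Klf15, a transcription factor of fat and muscle metabolism, on chromosome 6 from 90451552 to 90451782. It was annotated as intergenic and had 738 scaled reads in BAT, 187 in eWAT and 179 in iWAT. The lists held 51015 regions in eWAT, 50456 in iWAT and 15042 in BAT, with median values of 35.3, 35.7 and 30.4. The lowest listed regions rested on 17 reads in eWAT, 29 in iWAT and 6 in BAT.

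Genes of fat storage and of brown fat alike held regions listed in all 3 depots. At Acot1, a thioesterase of fatty acid metabolism, the promoter region on chromosome 12 from 85350049 to 85350279 had 196, 116 and 130.0 scaled reads in eWAT, iWAT and BAT. Ppargc1a, a coactivator of mitochondrial genes, had an intergenic region on chromosome 5 from 51987000 to 51987230 with 145, 92.0 and 71.9. A region upstream of Pfkl, a glycolytic enzyme, on chromosome 10 from 77475534 to 77475764 and annotated as intergenic, had 130, 132 and 74.7. Cpt1a admits fatty acids to mitochondria, and its intronic region on chromosome 19 from 3334179 to 3334409 had 125, 142 and 44.2. Insr, the insulin receptor, had an intronic region on chromosome 8 from 3240830 to 3241060 with 105, 134 and 41.5. The intronic region of Nfia, a factor of the brown fat program, on chromosome 4 from 97481260 to 97481490 had 132, 105 and 55.3. An intergenic region of Dpt, a matrix protein gene, on chromosome 1 from 166696921 to 166697151 had 178, 149.8 and 63.6. One of Meox2, a homeobox gene, on chromosome 12 from 37799275 to 37799505 had 127 in eWAT and 47.0 in BAT. That of Atp5g3, a mitochondrial protein gene, on chromosome 2 from 73757910 to 73758140, annotated as intergenic, had 102, 93.5 and 58.1. In total, 11034 regions (15.9%) were listed in all 3 depots, and their median values were 60.9, 59.4 and 33.2. Another 23021 (33.1%) were listed in eWAT and iWAT, 16130 (23.2%) in eWAT alone, 15406 (22.1%) in iWAT alone and 2183 (3.14%) in BAT alone. Of the eWAT regions, 66.8% (66.4 to 67.2%) were listed in iWAT and 23.3% (22.9 to 23.7%) in BAT. For iWAT regions, 67.5% (67.1 to 68.0%) were listed in eWAT and 23.9% (23.5 to 24.3%) in BAT. BAT regions were listed in eWAT in 78.9% (78.3 to 79.6%) and in iWAT in 80.0% (79.4 to 80.7%). Random placement gave at most 1.11%. With all lists at 15042 regions, eWAT and iWAT shared 61.5% (60.8 to 62.3%), BAT and eWAT 43.1% (42.3 to 43.9%) and BAT and iWAT 42.7% (41.9 to 43.5%). Equal size did not make the lists equal in strength. The eWAT and iWAT lists then ended at 53.0 and 53.6 scaled reads, while the BAT list still ran down to 16.6.

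**Figure D1:**
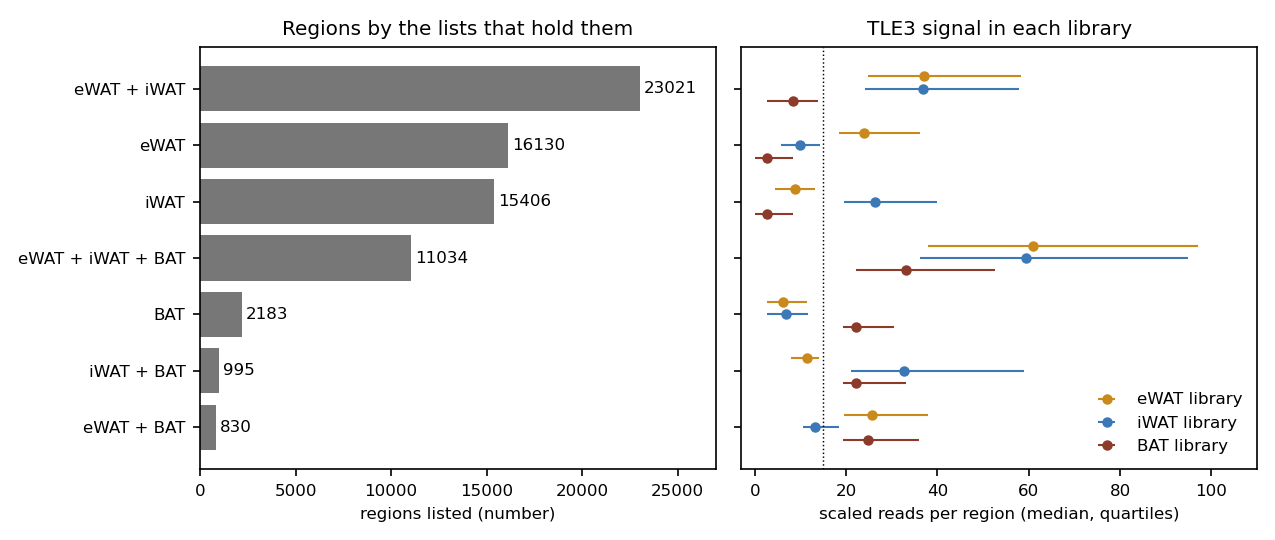
Number of regions by the lists that hold them, and the median with quartiles of scaled reads in each library for each group, with a dotted line at 15 scaled reads. The 16130 regions listed in eWAT alone had a median of 9.98 scaled reads in iWAT, below the line but not at 0.

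Regions missing from the eWAT or iWAT list still carried reads in that library. The 16960 eWAT regions not listed in iWAT had a median of 9.98 scaled reads in iWAT and 24.7 in eWAT, and 20.7% of them reached 15 in iWAT. The 16401 iWAT regions not listed in eWAT had medians of 8.83 in eWAT and 26.3 in iWAT. Of the 39151 eWAT regions not listed in BAT, 22.8% had 0 reads in BAT, and the medians were 5.53 in BAT and 30.9 in eWAT. A BAT value of 0 leaves room for 8.30 scaled reads.

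Hoxa5, a homeobox gene that marks body position, carried the strongest eWAT-selective site among listed genes. It lay in the 5′ untranslated region on chromosome 6 from 52154287 to 52154517 and had 183 scaled reads in eWAT, 26.8 in iWAT and 22.1 in BAT. Tcf7l2, a DNA-binding partner of β-catenin, held separate selective sites in 2 depots. The intronic eWAT site on chromosome 19 from 55940777 to 55941007 had 144, 42.6 and 19.4, and the intronic iWAT site from 55843426 to 55843656 had 11.5, 83.0 and 11.1. Acsl1, which activates fatty acids, had an intergenic eWAT site on chromosome 8 from 47519064 to 47519294 with 115, 27.3 and 11.1. Among eWAT-selective sites, Nr1h3, an oxysterol receptor gene, had a promoter site on chromosome 2 from 91035261 to 91035491 with 98.9, 55.7 and 33.2. Tle3 had an intergenic eWAT site on chromosome 9 from 61216425 to 61216655 with 116, 72.0 and 74.7, and Hadh, a fatty acid oxidation enzyme, an intronic one on chromosome 3 from 130974124 to 130974354 with 97.1, 60.4 and 11.1. Ndufb4, a complex I subunit gene, had an intergenic eWAT site on chromosome 16 from 37684732 to 37684962 with 112, 92.5 and 33.2, where the input of 11.1 kept the iWAT value below 10 times the input. Pik3r1, a regulatory subunit of the insulin signalling kinase, had an intergenic eWAT site on chromosome 13 from 102581835 to 102582065 with 97.1, 45.2 and 33.2 and an intronic iWAT site from 102498311 to 102498541 with 71.5, 92.5 and 36.0. In iWAT the intronic site of Ebf3, an early B cell factor gene, on chromosome 7 from 144495662 to 144495892 had 10.6, 117 and 27.6. Wt1, which encodes a transcription factor of visceral mesothelium, had an intronic iWAT site on chromosome 2 from 105008475 to 105008705 with 23.8, 101 and 5.53. Adipoq, the adiponectin gene, had an intergenic iWAT site on chromosome 16 from 23162262 to 23162492 with 10.6, 82.5 and 2.77. The intergenic site of Mmp2 on chromosome 8 from 95321446 to 95321676 had 7.06, 86.7 and 2.77, and that of Rxra, the partner of PPARγ, on chromosome 2 from 27527676 to 27527906 had 38.9, 81.5 and 11.1. Cox6c had an iWAT site on chromosome 15 from 35858249 to 35858479, annotated as intronic, with 43.3, 78.3 and 16.6. In BAT the promoter site of Tle1 on chromosome 4 from 71861758 to 71861988 had 41.5, 60.4 and 105, and an intronic site of Tle3 on chromosome 9 from 61261819 to 61262049 had 8.83, 7.88 and 58.1. Of the strongest 25% of each list, 1329 of 12854 eWAT regions (10.3%, 9.82 to 10.9%), 1617 of 12775 iWAT regions (12.7%, 12.1 to 13.2%) and 223 of 3887 BAT regions (5.74%, 5.05 to 6.51%) were selective. Another library still reached 15 scaled reads in 1082, 861 and 149 of them. Both other libraries stayed below 7.5 in only 60, 235 and 25. The median input was 4.56, 3.25 and 3.90 at the selective regions, against 1.30 over each full list. As at Ndufb4, the limit of 10 times the input kept another library off the list at most named sites. Among them were Nr1h3 (input 8.46), the Tle3 eWAT site (9.11), Hadh (7.16), the Pik3r1 iWAT site (7.16) and Tle1 (7.16). The same held at Hoxa5 (5.21), Acsl1 (7.16) and the eWAT sites of Tcf7l2 (5.86) and Pik3r1 (6.51). It also held at Ebf3 (3.25), Wt1 (3.25), Rxra (4.56) and Cox6c (4.56). Only at Mmp2, Adipoq, the Tcf7l2 iWAT site and the Tle3 BAT site did no other library reach 15 scaled reads. With the 3760 strongest regions of each list, 4.36%, 6.22% and 5.61% were selective (164, 234 and 211), and the BAT share was no longer the lowest.

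Most TLE3 regions lay far from start sites. In eWAT 3.17%, in iWAT 2.60% and in BAT 3.68% of regions were within 1 kb of a start site. Introns held 46.6%, 44.5% and 45.0%, and intergenic sequence held 48.2%, 51.1% and 49.4%. The median distance was 35.0 kb, 42.0 kb and 36.8 kb. Promoter regions nevertheless included strong ones, such as those of Hes1, a Notch target, and Acot1. The Hes1 promoter region on chromosome 16 from 30065184 to 30065414 had 117 scaled reads in eWAT, 147 in iWAT and 47.0 in BAT. With an input of 10.4 there, the BAT value missed the limit of 10 times the input. Regions listed in BAT alone were nearest to start sites, with 8.61% (7.51 to 9.86%) within 1 kb, against 3.47% (3.19 to 3.76%) for eWAT alone and 1.75% (1.55 to 1.97%) for iWAT alone.

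Adipocyte genes often had TLE3 regions nearby. Cd36 and Lpl are named here after their values were seen. Of 35 genes of adipocyte identity and lipid storage, 34 had a listed region within 50 kb in eWAT, 33 in iWAT and 26 in BAT. Pparg had 21, 19 and 7 such regions, Cd36, a fatty acid transporter, had 13, 11 and 8, and Lpl, the lipase that unloads lipoproteins, had 12, 9 and 4. No random list out of 10000 reached the share of this list in any depot, and the share over all 20953 genes was 48.1%, 44.3% and 22.4%. Random lists were not matched on expression, which was not measured here. Percentiles of shares thus do not separate adipocyte genes from other genes active in the cultures. Fibroblast genes reached percentiles of 100, 99.8 and 99.9. Glucose uptake, glycolysis and insulin signalling genes reached 31, 30 and 19 of 35, at or above percentile 99.99 in each depot, with Insr at 9, 10 and 7 regions. Adipocyte transcription factors reached 32, 31 and 20 of 36 and white-selective genes 17, 16 and 11 of 20, and the lowest percentile of these 6 shares was 99.9. Ccl2, a monocyte chemokine in the white-selective list, had 8, 8 and 4 regions. Thermogenic genes reached 29, 25 and 18 of 38 (percentiles 99.96, 98.7 and 99.9). With lists of the size of the BAT list they fell to 12 in eWAT (percentile 80.9) and 13 in iWAT (94.3), and white-selective genes fell to percentile 94.0 in iWAT. Among them, Ucp1, the uncoupling protein of brown fat, had 3, 3 and 1, Cidea, a lipid droplet protein, had 2, 3 and 2, and Ppargc1a had 7, 5 and 3. The strongest BAT value at Ucp1, 58.1, was not at the listed BAT region, which had 44.2. With an input of 7.16 there, it missed the limit of 10 times the input. Prdm16 and Hoxc9 had 0 regions under the nearest start site rule. All 6 Groucho genes had a region in eWAT and in iWAT and 5 in BAT (percentiles 99.5, 99.8 and 99.9).

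Nuclear-encoded mitochondrial genes stood out less. Nuclear oxidative phosphorylation genes reached 32, 28 and 13 of 78 (percentiles 70.9, 63.2 and 56.1), and mitochondrial biogenesis genes 12, 10 and 6 of 20 (68.0, 44.7 and 62.6). Exceptions with several regions were Atp5g3, an ATP synthase subunit gene with 7, 9 and 3, and Tomm20, a mitochondrial import receptor gene with 5, 3 and 2. Fatty acid oxidation genes reached 19, 16 and 12 of 29 (92.1, 77.8 and 97.9), and their eWAT and iWAT percentiles were 99.6 and 98.5 within 10 kb, 87.0 and 79.6 within 100 kb and 79.2 and 63.4 with equal-sized lists. Depot-developmental factors reached 12, 14 and 8 of 22 (67.3, 92.7 and 89.1), and their iWAT percentile was 97.1 within 100 kb, 36.8 within 10 kb and 98.9 with random lists matched on length alone, where the BAT percentile was 96.4. Wnt-TCF and Notch targets reached 15, 16 and 11 of 25 (73.4, 90.1 and 97.0). For the Wnt and Notch targets the iWAT percentile was 99.98 with equal-sized lists, 99.4 within 10 kb and 98.6 within 100 kb, and the eWAT percentile within 100 kb was 97.2. Axin2, a Wnt feedback gene, had 7, 6 and 3, and Hes1 had 5, 5 and 2. Across all 18 lists, 9 eWAT shares, 8 iWAT shares and 9 BAT shares were above the 95th percentile, where 2.7 of the 54 would be by chance.

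**Figure D2:**
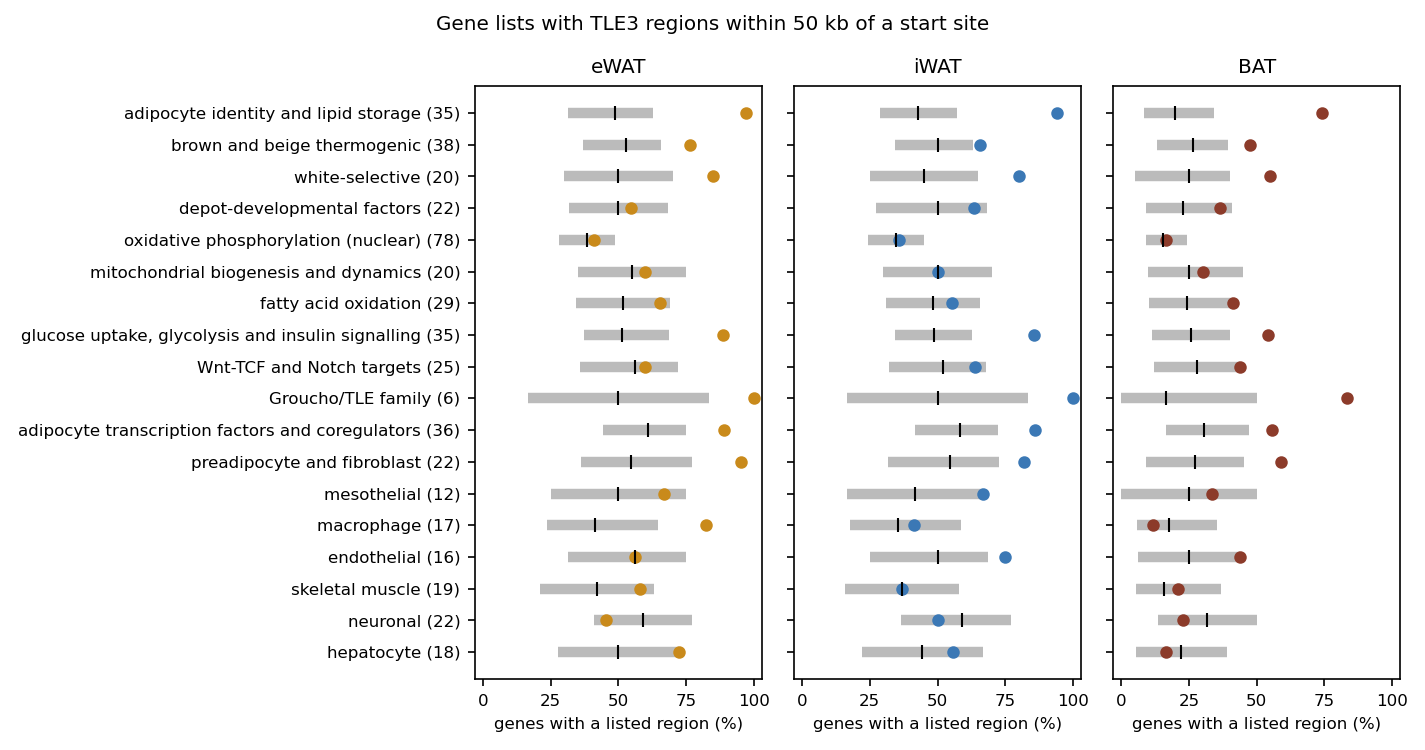
Percent of the genes of each list with a listed TLE3 region within 50 kb in each depot (dots), with the median (tick) and central 95% (grey) of 10000 random lists. Adipocyte identity genes lay above the grey range in all 3 depots, while oxidative phosphorylation genes stayed within it.

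Between eWAT and iWAT, some of the largest differences at listed genes were at developmental genes. Tbx15, a T-box factor of subcutaneous and brown fat, had 42.4 scaled reads in eWAT and 588 in iWAT, a log2 ratio of −3.96 (−4.40 to −3.54) for eWAT over iWAT relative to the median gene. All log2 ratios are given relative to the median gene, which was 0.16 for eWAT over iWAT, −1.54 for BAT over eWAT and −1.49 for BAT over iWAT. Lgr5, Irx5, Tbx5, Fasn, Cd36, Lpl, Retn, Elovl6, Tle4, Dio2, Esrrg, Thy1, Lum, Col1a2 and Pi16 were chosen for this comparison from the gene lists after their values were seen. Lgr5, a stem cell receptor and Wnt target, had 7.95 and 213 (−4.91, −6.05 to −3.97). Irx5, a homeobox factor, had 11.5 and 72.5 (−2.82, −3.77 to −2.00). Tbx5, a T-box factor of heart and forelimb, had 20.3 and 76.2 (−2.07, −2.77 to −1.43). The nearest regions of Irx5 and Tbx5 lay 15.7 kb and 33.6 kb from their start sites. Lgr5, Irx5 and Tbx5 thus had no value within 10 kb. Ebf3 had 110.4 and 425 (−2.11, −2.39 to −1.84), and Ebf2, which marks brown preadipocytes, had 260.5 and 360.0 (−0.63, −0.83 to −0.43). Wt1, a visceral marker, also ran lower in eWAT with 189.9 and 326 (−0.94, −1.17 to −0.72), but within 10 kb of its start site the ratio reversed to 2.67. Hoxa5 ran the other way with 183 and 26.8 (2.61, 2.16 to 3.08). Among 12 measured depot-developmental factors, 6 were lower and 1 higher in eWAT under every scaling. Their median was −0.66, at percentile 0.19 of random lists, and it came within the central 95% when only regions within 10 kb counted (percentile 9.00) or genes with a mean of at least 100 (13.0). Fibroblast genes ran the same way, with a median of −0.35 and 9 lower and 4 higher of 21 measured.

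**Figure D3:**
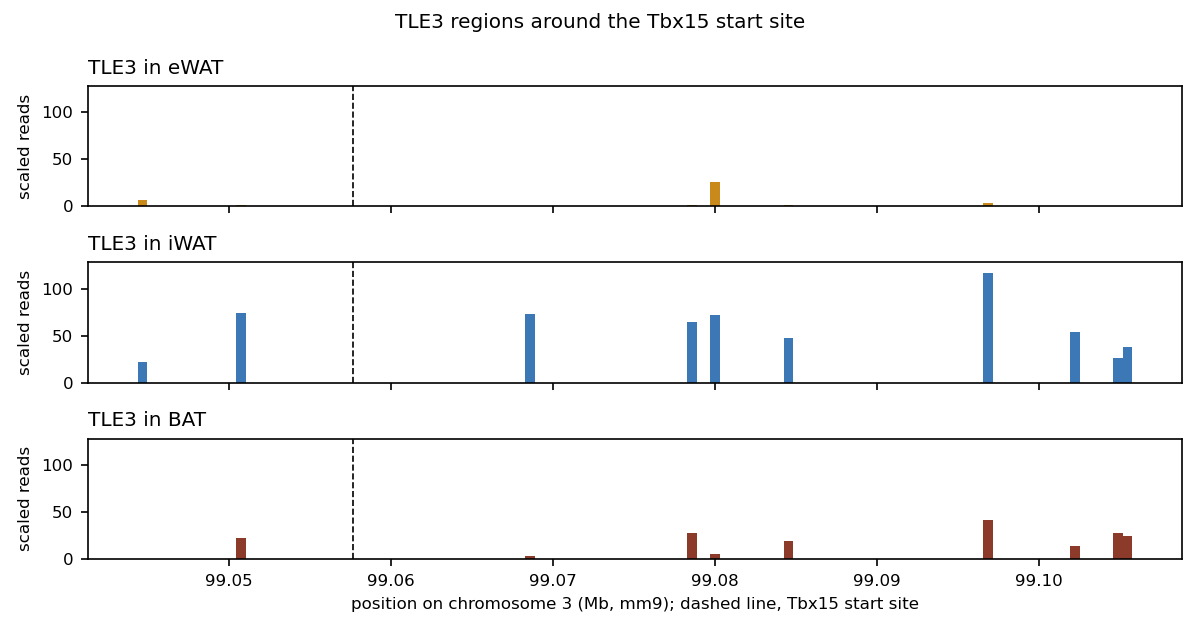
Scaled reads of each region along chromosome 3 within 50 kb of the Tbx15 start site in the eWAT, iWAT and BAT libraries, with a dashed line at that site. The strongest iWAT region within 50 kb, from 99096722 to 99096952 in an intron, had 116 scaled reads in iWAT, 41.5 in BAT and 3.53 in eWAT.

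Lipid storage genes leaned toward eWAT. Fasn, the fatty acid synthase, had 230.5 scaled reads in eWAT and 128 in iWAT (0.68, 0.43 to 0.94), and Fabp4, a fatty acid carrier, had 244 and 158 (0.46, 0.22 to 0.70). Cd36 had 722 and 551 (0.23, 0.09 to 0.36) and Lpl 679 and 511 (0.25, 0.11 to 0.39). Retn, which encodes the adipokine resistin, had 445 and 320.0 (0.31, 0.14 to 0.49), and Acsl1 had 469.8 and 296 (0.50, 0.33 to 0.68). Adipoq went against the list with 359 and 435 (−0.44, −0.61 to −0.26), as did Elovl6, a fatty acid elongase, with 151 and 239 (−0.83, −1.09 to −0.57). Pparg had 1239 and 1161 (−0.07, −0.17 to 0.03) and Lep, the leptin gene, 79.5 and 90.9 (−0.36, −0.74 to 0.02). Of 32 measured adipocyte identity genes, 15 were higher and 4 lower in eWAT under every scaling, and the median of 0.24 lay at percentile 99.6, or 95.3 with regions within 100 kb. Fibroblast genes went the opposite way and macrophage genes the same way, with medians of −0.35 and 0.64. How far each culture had differentiated was not analysed here. Tle3 itself had 1415 and 893 (0.50, 0.40 to 0.60) and Tle2 309.9 and 223 (0.31, 0.10 to 0.52), while Tle4 had 193 and 323 (−0.90, −1.13 to −0.68).

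Thermogenic genes were divided between the white depots. Cidea had 72.4 scaled reads in eWAT and 96.2 in iWAT (−0.57, −0.97 to −0.19), which reversed to 0.79 within 10 kb, and Dio2, which activates thyroid hormone, had 81.2 and 131 (−0.86, −1.22 to −0.51). Ucp1 had 212 and 178 (0.09, −0.15 to 0.33) and Ppargc1a 325 and 265 (0.13, −0.07 to 0.33). Esrrg, an orphan nuclear receptor gene, was higher in eWAT with 50.3 and 13.7 (1.72, 1.03 to 2.45). In this list 4 genes were higher and 4 lower under every scaling, and its median of 0.08 was at percentile 74.9. Oxidative phosphorylation genes had 6 higher and 6 lower (median −0.06, percentile 33.1). Cox6c, a cytochrome oxidase subunit, was lower in eWAT with 221 and 319 (−0.69, −0.91 to −0.48).

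Fibroblast genes leaned toward iWAT. Thy1, a surface marker of stromal cells, had 47.7 scaled reads in eWAT and 191 in iWAT (−2.16, −2.60 to −1.75). Lum, a matrix proteoglycan, had 110.4 and 287 (−1.54, −1.83 to −1.26), Col1a2, a collagen chain, 145 and 264 (−1.03, −1.29 to −0.77), and Mmp2, a matrix protease, 354 and 482 (−0.61, −0.78 to −0.44). Pi16, a marker of fibroblast progenitors, was higher in eWAT with 139.5 and 35.7 (1.80, 1.38 to 2.23). Of 21 measured genes, 9 were lower and 4 higher in eWAT under every scaling, with a median of −0.35 at percentile 1.02. Macrophage genes leaned toward eWAT, with 6 of 7 higher and 0 lower and a median of 0.64 at percentile 99.1, or 93.9 within 10 kb. The other medians stayed within the central 95% of random lists. They were 0.16 for white-selective genes, 0.20 for mitochondrial biogenesis, 0.09 for fatty acid oxidation, 0.14 for glucose and insulin genes, −0.17 for Wnt and Notch targets, 0.19 for the Groucho family and −0.02 for transcription factors.

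**Figure D4:**
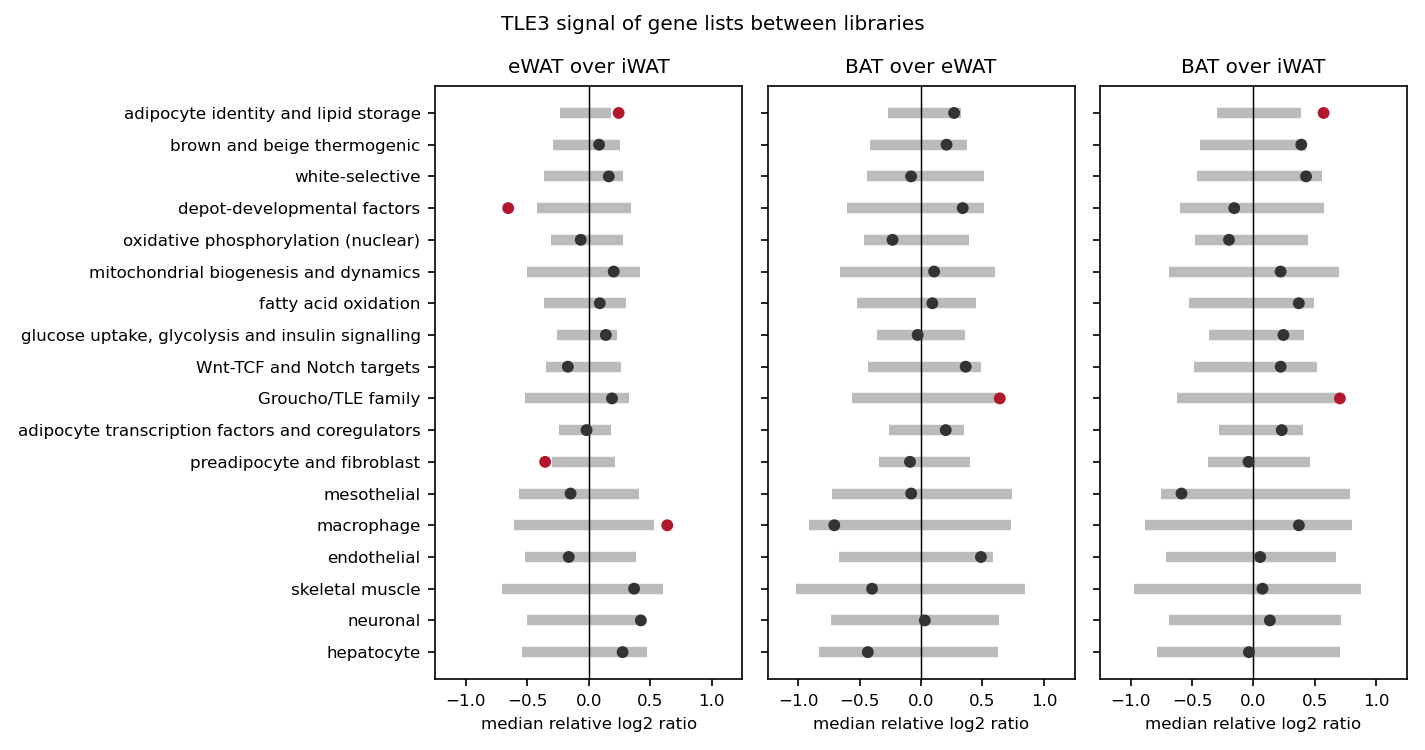
Median log2 ratio of each gene list relative to the median gene for the 3 depot pairs (dots), with the central 95% of 10000 random lists in grey and lists outside it in red. Depot-developmental factors were at −0.66 and macrophage genes at 0.64 for eWAT over iWAT.

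Genes chosen after their values were seen, as the most extreme with at least 3 regions, included Wnt4, a Wnt ligand gene, with 101 scaled reads in eWAT and 8.41 in iWAT (3.42, 2.66 to 4.27). Chdh, a choline oxidation gene, had 198 and 40.5 (2.13, 1.75 to 2.52), and Daam2, a formin of Wnt signalling, had 338 and 82.0 (1.88, 1.61 to 2.16). Prdm6, a PR domain gene of smooth muscle, had 26.5 and 202 (−3.09, −3.68 to −2.55), and Popdc3, a Popeye domain gene, had 14.1 and 140.3 (−3.47, −4.30 to −2.75). Over all regions, the exact test called 15556 (22.4%) higher and 20381 (29.3%) lower in eWAT than in iWAT, and the split was 18753 and 18180 under the authors' scaling and 15317 and 20641 relative to the common regions. The test compares those libraries, not the conditions. Of 9099 measured genes, 2534 were higher and 2099 lower under every scaling.

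Tbx15, Lgr5 and Irx5 were higher in BAT than in eWAT, while their direction against iWAT depended on the scaling. Tbx15 had 185 scaled reads in BAT, a log2 ratio of 3.67 (3.11 to 4.23) over eWAT and −0.18 (−0.55 to 0.18) over iWAT, the latter −1.67 under the authors' scaling. Lgr5 had 71.9 (4.71, 3.58 to 5.99 over eWAT and −0.08, −0.71 to 0.50 over iWAT), and Irx5 had 41.5 (3.39, 2.22 to 4.58 over eWAT). Zic1, a zinc finger gene known from brown fat, had 27.6 in BAT from 10 reads, 3.53 in eWAT and 1.05 in iWAT (4.51, 2.71 to 6.63 over eWAT and 6.21, 3.98 to 9.44 over iWAT). Hoxa5 was lower than in eWAT (−1.51, −2.74 to −0.50), and Tbx5 had 0 reads in BAT. BAT directions are stated for genes only where they held under every scaling. Lgr5, Irx5, Tbx5, Uqcrc1, Ctbp2, Thy1, Ppara, Acsl5, Esrrg and Tle6 were chosen from the lists after their values were seen.

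Several genes had more signal in BAT, most of it at 1 or 2 regions, by an amount that depended on the scaling. Under the authors' scaling the log2 ratios over eWAT and over iWAT were 0.93 and 1.04 for Klf15, 0.45 and 0.84 for Heyl, 1.15 and 1.36 for Atp5g1 and 0.23 and 0.21 for Ccl2. Klf15 had 1073 scaled reads in BAT, 564 in eWAT and 521 in iWAT (2.46, 2.28 to 2.65 over eWAT and 2.53, 2.36 to 2.70 over iWAT), and the region 39.0 kb from its start site held 738 of the 1073. Heyl, a Notch target, had 329, 240.2 and 184 (1.99, 1.67 to 2.31 and 2.33, 2.02 to 2.63), of which 318 were in the intergenic region on chromosome 4 from 122903081 to 122903311. Atp5g1, an ATP synthase subunit gene, had 354, 159 and 138 (2.69, 2.35 to 3.03 and 2.85, 2.53 to 3.16), with 271 in the intergenic region on chromosome 11 from 95931724 to 95931954. Ccl2 had 785, 668 and 679 (1.77, 1.57 to 1.97 and 1.70, 1.51 to 1.89), with 395 in the intergenic region on chromosome 11 from 81820377 to 81820607. Uqcrc1, a complex III subunit gene, went the other way, with 2.77 in BAT, 129.8 in eWAT and 108 in iWAT (−4.02, −9.33 to −1.51 and −3.80, −9.11 to −1.31). Ctbp2, a corepressor gene, was lower than in eWAT with 16.6 and 229 (−2.25, −3.71 to −1.11). Thy1 was lower than in iWAT with 5.54 and 191 (−3.62, −6.67 to −1.76). Higher than in iWAT alone were Ppara, a nuclear receptor of fatty acid oxidation (2.17, 1.52 to 2.79), Acsl5, a fatty acid activating enzyme (2.33, 1.74 to 2.88), Esrrg (2.77, 1.65 to 3.81) and Tle6 (1.97, 1.59 to 2.35).

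**Figure D5:**
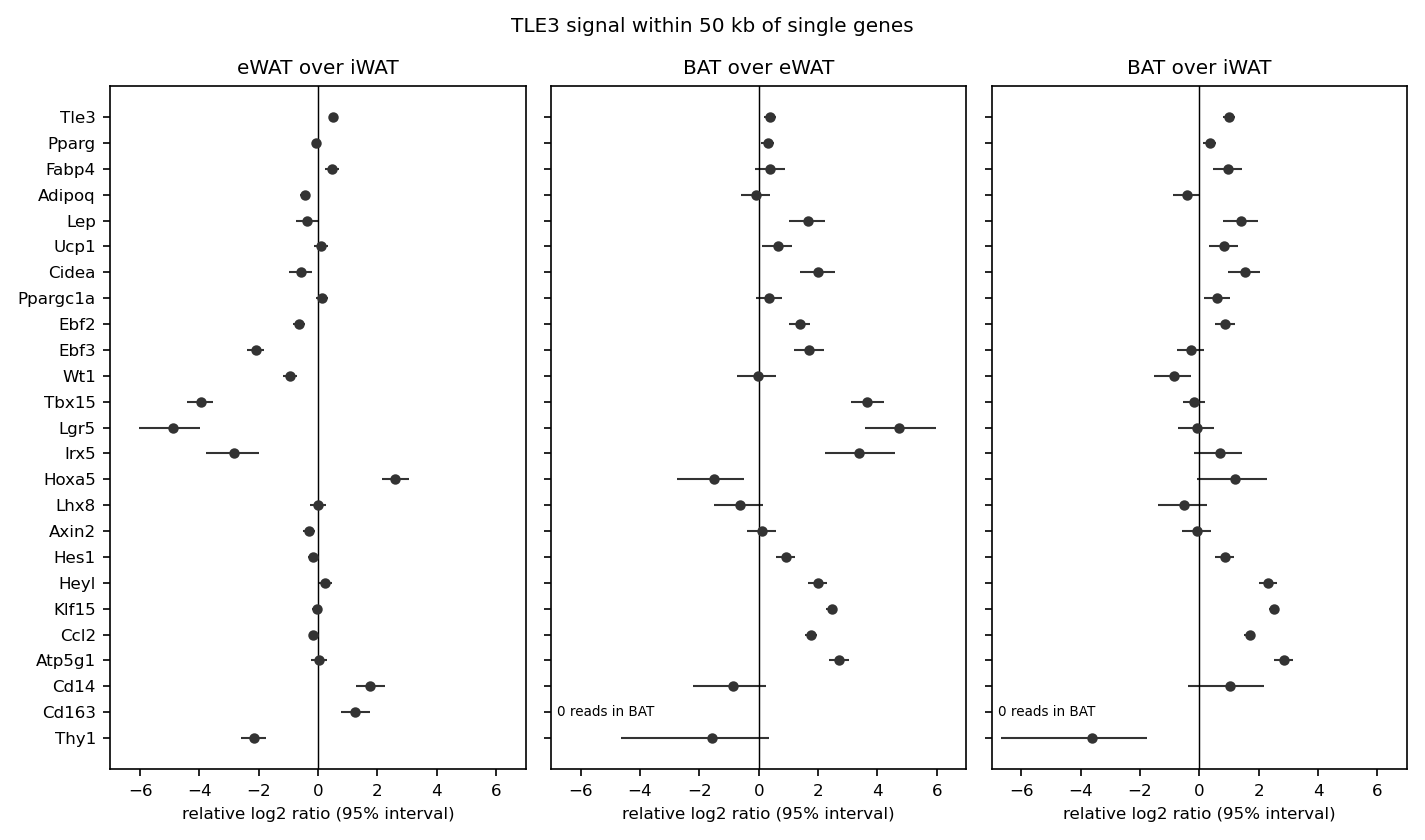
Log2 ratios relative to the median gene, with 95% exact intervals from read counts, of 25 genes for the 3 depot pairs. Tbx15 was at −3.96 for eWAT over iWAT and 3.67 for BAT over eWAT.

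The BAT ratios of Ucp1, Cidea, Ppargc1a, Pparg, Tle3, Lep and Lhx8 had no direction that held under every scaling. Of 24 measured thermogenic genes, 2 were higher and 0 lower in BAT than in iWAT under every scaling. Over eWAT, 0 were higher and 0 lower. Ucp1 had 113 scaled reads in BAT (0.64, 0.12 to 1.12 over eWAT and 0.84, 0.34 to 1.31 over iWAT), Cidea 99.5 (2.00, 1.39 to 2.58 and 1.54, 0.98 to 2.06) and Ppargc1a 144 (0.36, −0.09 to 0.78 and 0.61, 0.17 to 1.02). Pparg had 525 (0.30, 0.07 to 0.52 and 0.34, 0.12 to 0.56), Tle3 636 (0.38, 0.18 to 0.58 and 1.00, 0.79 to 1.20) and Lep 85.7 (1.65, 1.01 to 2.25 and 1.40, 0.80 to 1.96). Lhx8, a LIM homeobox gene linked to brown fat, had 38.7 (−0.62, −1.52 to 0.16 and −0.52, −1.41 to 0.25). Of the 32 adipocyte identity genes, 0 had a direction under every scaling, yet their median over iWAT was 0.57 at percentile 99.9 and over eWAT 0.27 at percentile 93.7. The 6 Groucho genes had medians of 0.64 over eWAT and 0.70 over iWAT, at percentiles 97.7 and 97.7. Over eWAT the Groucho median came within the central 95% with a pseudocount of 1 (percentile 97.1) and with a mean of at least 100 (95.2), and over iWAT with a pseudocount of 20 (97.0) and within 100 kb (87.7).

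All other medians of the 18 fixed lists lay within the central 95% of random lists with regions within 50 kb. Over eWAT and over iWAT they were 0.21 and 0.39 for thermogenic genes, −0.08 and 0.43 for white-selective genes, 0.34 and −0.16 for depot-developmental factors, −0.23 and −0.20 for oxidative phosphorylation and 0.11 and 0.22 for mitochondrial biogenesis. They were 0.09 and 0.37 for fatty acid oxidation, −0.03 and 0.24 for glucose and insulin genes, 0.36 and 0.22 for Wnt and Notch targets, 0.20 and 0.23 for transcription factors, −0.09 and −0.04 for fibroblast genes and −0.71 and 0.37 for macrophage genes. Wnt and Notch targets over eWAT lay above that range at 10 kb and 100 kb. Thermogenic and fatty acid oxidation genes over iWAT did so at 100 kb. Of 54 list medians over the 3 pairs, 7 were outside the central 95%, where 2.7 would be by chance. Of 9099 genes, 145 were higher and 874 lower in BAT than in eWAT under every scaling, and 187 were higher and 532 lower than in iWAT. These counts do not weigh higher against lower, because the bars were unequal. Under the authors' scaling the median gene was at −1.54 over eWAT and −1.49 over iWAT. The medians over all regions were −1.81 and −1.94. A gene called higher thus had to lie further from the median gene than a gene called lower. The region test called 5460 regions higher and 2246 lower in BAT than in eWAT, against 1956 and 32618 under the authors' scaling and 3245 and 10013 relative to the common regions. For BAT over iWAT it called 5998 and 2187, against 2006 and 34262 and 3251 and 14059. Genes chosen after their values were seen were Ncs1, a neuronal calcium sensor gene, with 312 scaled reads in BAT, 68.9 in eWAT and 77.2 in iWAT (3.72, 3.29 to 4.15 and 3.50, 3.14 to 3.87), and Atp8a1, a phospholipid flippase gene, with 265, 113 and 113 (2.77, 2.37 to 3.16 and 2.72, 2.36 to 3.07). Hhex, a homeobox gene, had 2.77, 131 and 102 (−4.03, −9.34 to −1.52 and −3.72, −9.03 to −1.22).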

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

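Of the values that were varied for the main results, 61 stayed the same and 50 moved. Alternatives added after the data were seen were the 20-fold limit, the scalings and the settings of the gene ratios. With at least 20-fold over the input, eWAT kept 33771 regions and BAT 8387, 5707 were common to all 3 depots, and the shares were 61.2% for eWAT regions in iWAT, 18.6% for eWAT in BAT, 60.5% for iWAT in eWAT, 18.6% for iWAT in BAT, 75.0% for BAT in eWAT and 75.6% for BAT in iWAT. A limit of 8-fold removed nothing, because every listed region had at least 10-fold. Its outcomes were thus fixed in advance, and they are counted among the 61. The overlap rules were hardly a test either, because the lists drew on the same regions. Of 34086 eWAT regions shared with iWAT, 34055 were the identical region. Asking for more overlap or nearer centres could thus barely move the shares, and those outcomes also count among the 61. For the strongest 25% of the query list the same 6 shares were 89.0%, 45.7%, 85.4%, 45.0%, 91.2% and 90.9%. Ranked by fold over the input, equal-sized lists shared 54.4% for eWAT and iWAT, 39.5% for BAT and eWAT and 37.5% for BAT and iWAT, and 2676 iWAT and 446 BAT regions were selective. The strongest 10000 regions shared 59.7% for eWAT and iWAT and 44.6% for BAT and eWAT. The strongest 5000 shared 55.4%, 45.7% for BAT and eWAT and 41.3% for BAT and iWAT. In the strongest 10%, 296 eWAT, 383 iWAT and 61 BAT regions were selective. With the same number of strongest regions from each list, 3760, the selective regions were 164 in eWAT, 234 in iWAT and 211 in BAT. Within 500 bp of a start site lay 1.74% of eWAT, 1.36% of iWAT and 2.27% of BAT regions, and within 5 kb 12.8%, 10.9% and 12.7%. Under the authors' scaling, 1956 regions were higher and 32618 lower in BAT than in eWAT, and 2006 higher and 34262 lower than in iWAT. Relative to the common regions these were 3245, 10013, 3251 and 14059.

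The number of gene lists outside the central 95% was 2 for eWAT over iWAT and 2 for BAT over eWAT at 10 kb. It was 0 for BAT over eWAT with a pseudocount of 1, 1 for BAT over iWAT with a pseudocount of 20, and 0 for BAT over eWAT and 1 for BAT over iWAT with a mean of at least 100. Fibroblast genes held in eWAT over iWAT in every setting, and adipocyte identity genes in every setting but 100 kb (percentile 95.3). Depot-developmental factors were at percentile 9.00 at 10 kb and 13.0 with a mean of at least 100, and macrophage genes at 93.9 at 10 kb. Wnt and Notch targets were at 99.9 at 10 kb and 99.7 at 100 kb in BAT over eWAT, and thermogenic and fatty acid oxidation genes were each at 99.7 at 100 kb in BAT over iWAT. Lists whose share of genes with a listed region was above that of 95% of random lists numbered 9 in eWAT, 8 in iWAT and 9 in BAT. They numbered 6 in eWAT and 7 in iWAT with equal-sized lists, 11, 9 and 8 within 10 kb, 12, 10 and 10 within 100 kb, and 9, 10 and 10 with matching on length alone. Equal-sized lists took macrophage genes in eWAT to percentile 85.0. For named genes, 72 ratios moved, 3 reversed and 110 stayed at 10 kb, and 34 moved, 2 reversed and 227 stayed at 100 kb. The reversed ones were Wt1 (2.67), Cidea (0.79) and Rflna (−4.46, chosen after its values were seen) in eWAT over iWAT at 10 kb, and Rxra at 100 kb in BAT over eWAT (1.19) and over iWAT (1.19). Distal regions dropped at 10 kb and added at 100 kb changed which regions these genes were given. The cause of the other changes was not tested. No paired analysis was possible because each depot had 1 library and no label pairs them. The fold over local background, motifs and random positions of the annotation were not run.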

Other observations

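The tests with genes of tissues not in the culture and with lower signal over background in BAT, its values at the common regions included, were chosen only after those results were seen.

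Of 17 macrophage genes, 14 had a listed region in eWAT, 7 in iWAT and 2 in BAT (percentiles 99.96, 61.3 and 23.4). With equal-sized lists these were 5, 1 and 2, and the eWAT percentile was 85.0. The macrophage genes named next were chosen after their values were seen. Mpeg1, a perforin-like gene of phagocytes, had 229.6, 157 and 91.2 scaled reads, and Ptprc, the pan-leukocyte marker, had 145, 81.5 and 22.1. Cd14, a lipopolysaccharide co-receptor, had 102, 26.8 and 19.4, and Cd163, a scavenger receptor, had 83.9, 31.5 and 0. In the second macrophage list 35, 21 and 6 of 40 genes had a region (percentiles 100, 78.2 and 9.6). Of that list, Lcp1, a leukocyte actin bundler, had 153.7, 41.0 and 19.4, and Fcgr3, an Fc receptor, had 236.7, 179 and 52.5. Of its 35 genes with regions, 24 were higher and 1 lower in eWAT than in iWAT under every scaling. The lower one was Laptm5, a lysosomal membrane protein gene, with 54.8, 87.2 and 44.3. T and NK cell genes reached 12, 7 and 4 of 22 (72.7, 13.4 and 37.3) and B cell genes 4, 4 and 0 of 12 (27.6, 40.7 and 4.28). Over eWAT, BAT medians were −0.78 for the second macrophage list (percentile 0.05, outside the central 95%), −0.58 for T and NK cell genes and −1.54 for the 3 measured B cell genes, and over iWAT −0.34, −0.27 and −0.92.

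Other cell types were uneven. Fibroblast genes reached 21, 18 and 13 of 22 (100, 99.8 and 99.9), mesothelial genes 8, 8 and 4 of 12 (89.1, 94.3 and 81.2) and endothelial genes 9, 12 and 7 of 16 (60.2, 98.7 and 94.9). Skeletal muscle genes reached 11, 7 and 4 of 19 (92.6, 46.1 and 63.5), neuronal genes 10, 11 and 5 of 22 (7.77, 24.2 and 20.5) and hepatocyte genes 13, 10 and 3 of 18 (98.3, 85.8 and 32.8). Within 10 kb the percentile fell to 91.2 for fibroblast genes in BAT and 58.5 for endothelial genes in iWAT, and with equal-sized lists to 73.9 for hepatocyte genes in eWAT. In eWAT it rose to 99.6 within 10 kb and 96.0 within 100 kb for muscle genes, and to 98.9 within 100 kb for endothelial genes. Medians for eWAT over iWAT were −0.15 for mesothelial, −0.16 for endothelial, 0.37 for muscle, 0.42 for neuronal and 0.28 for hepatocyte genes. For BAT over eWAT they were −0.08, 0.49, −0.40, 0.03 and −0.43, and for BAT over iWAT −0.59, 0.05, 0.07, 0.13 and −0.04. Single regions chosen after their values were seen stood out in 1 depot. An intron of Alad, a heme synthesis gene, on chromosome 4 from 62176588 to 62176818 (mm9) had 170 scaled reads in eWAT, 4.73 in iWAT and 0 in BAT. An intron of Dach1, a transcription cofactor gene, on chromosome 14 from 98267857 to 98268087 had 0.88, 94.1 and 0. An intron of Igf1r, the receptor of insulin-like growth factor 1, on chromosome 7 from 75169624 to 75169854 had 1.77, 3.68 and 108. The promoter of Nnt, a mitochondrial transhydrogenase gene, on chromosome 13 from 120198069 to 120198299 had 185, 166 and 484.

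The higher signal at macrophage genes in eWAT may come from macrophage chromatin in the eWAT culture, which stays open. The second macrophage list lay at percentile 99.98 for eWAT over iWAT, although the first list fell to 93.9 within 10 kb. A second list in the same libraries repeats the higher signal and cannot tell its source. No sort or gate is named in the labels, and 0 genes of the macrophage lists stood in another list. Immune cells of other kinds stay open: the T and NK cell list (percentile 80.9) and the B cell list (61.1) rest on 7 and 3 measured genes, and of 13 T and NK cell genes with regions 7 were higher and 0 lower in eWAT under every scaling. A general rise at genes of tissues not in the culture stays open too, with neuronal genes at 97.1 and hepatocyte genes at 85.5. TLE3 binding at these genes in adipocytes themselves was not tested.

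Depth could have shortened the BAT list and stays open. After thinning to the BAT depth, 46232 and 46209 regions of the merged set passed both limits in eWAT and iWAT, whether listed there or not. These were at least 3.07 times the 15042 of BAT. The limits are in scaled reads, however, which thinning leaves alone on average, and peak calling was not redone. Lower signal over background in the BAT library is in line with input-subtracted BAT values of 0.349 and 0.338 of the eWAT and iWAT values at the regions strongest by mean, which the white depots weigh most. At the regions listed in all 3 depots the ratios were higher, 0.585 and 0.619. A biological difference of the depot would look the same with 1 library and stays open.

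Regions listed in BAT alone lay within 1 kb of start sites more often (8.61%), which might be noise at 6 reads. Those with 12 or more reads still had 13.5% (lower bound 10.8%, n = 504), which speaks against counting noise at that limit alone. Other nonspecific signal was not tested. The share was also higher among stronger regions of the other depots. With an own value of 30 or more it was 4.89% for eWAT alone and 2.16% for iWAT alone, against 3.47% and 1.75% over all. High input at start sites stays open: the fold over the input was 15.3 near start sites and 25.5 elsewhere, a ratio of 0.600, but this restates the higher iWAT input there, which makes the limit of 10 times the input harder to pass. Signal at start sites in every depot stays open: eWAT and iWAT values near start sites were 1.29 and 1 times those elsewhere, but regions listed in BAT alone were selected for low values in both. A difference of the depot was not tested.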
